A study of activated sludge metagenome with 12 samples.

How the data were processed

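The series profiled bacterial communities by full-length 16S rRNA gene amplicons read on the PacBio platform. Per the labels, total DNA came from an activated sludge inoculum and from mixed microbial cultures, in 12 samples that form 4 groups (Inoculum, Run 1, Run 2 and Run 3) of 3 replicates each. DNA was extracted with the DNeasy PowerSoil Kit and libraries were built with the SMRTbell Prep Kit 3.0 protocol. The series concerns phosphate limitation in the production of PHBV, a polyhydroxyalkanoate (PHA) copolymer, from a synthetic fermentation digestate, and its design names 3 ratios of carbon to phosphorus. No label says which run had which ratio, so the runs were compared by number and given no order. Nor do the labels say whether replicates are separate cultures or repeated samples of 1 culture, so p-values measure the spread between these samples only.

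The deposited feature table holds counts: whole numbers of reads per sequence feature and sample, with no normalization. The deposited taxonomy table gives a lineage per feature and a confidence stated as a fraction, per the file headers. The denoising or clustering tool, the classifier and the reference database are not given in the sources used here, and names such as midas_g_11604 are placeholder genus names taken from the taxonomy as it stands. The table holds 1246 features, all with a lineage. The smallest value above 0 was 2 in each library, so a feature seen once in a library is absent, and no share is given as an upper limit for a count of 0. Library totals ran from 6252 to 11451 reads. Wilson 95% intervals are given for shares reported for 1 library, and they cover counting error only, since PCR reads are not independent molecules. A share of 16S reads is not a share of cells, because copy number of the gene differs between taxa.

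Of the features, 1120 had a genus name and 126, with 1.79% of all reads, did not; the latter were pooled under their lowest named rank. Reads were summed into 457 genus labels, and those with at least 10 reads in total and reads in at least 2 samples were tested, which kept 257 genera and 98.3% of reads. Genera were compared with the edgeR quasi-likelihood test (edgeR 4.0.16 in R 4.3.3; glmQLFit and glmQLFTest) in 1 fit of all 12 samples with 8 residual degrees of freedom. Library size was the total of reads and normalization factors were 1, so that changes stay on the scale of relative abundance. Adjusted p-values are Benjamini-Hochberg values over the genera tested, two-sided, with a threshold of 0.05. The contrasts were each pair of runs, an F test among the 3 runs, each run against the inoculum, and the mean of the runs on the log scale against the inoculum. Fold changes are ratios of mean relative abundance. Against a group at 0 they are given as at least the ratio to 3 reads per library. That floor is a convention, since reads removed before deposit could raise a count of 0 by an unknown amount, while fitted log2 values for such genera depend on the prior count and are no bounds.

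The same test was run on the summed reads of 12 taxon lists (84 list tests adjusted together) and of 19 phyla (133 tests adjusted together). The lists were PHA-storing genera, polyphosphate-accumulating genera, glycogen-accumulating genera, nitrifying genera, filamentous genera, predatory bacteria, fermentative and gut genera, denitrifying sludge genera, Bacteroidota of enrichment cultures, stalked and budding bacteria, reagent contaminants and organelles. The PHA-storing list was fixed without Sphaerotilus. Lists share members and are not independent. edgeR pools the spread over lists, so the p-values of sums rest on more than the 8 residual degrees of freedom of the samples. Very small values are therefore no measure of strength. With only the groups compared, the adjusted p for filamentous genera in Run 3 against the inoculum went from 3.07e-37 to 9.44e-06. Of 162 list and phylum cases in that fit, 12 newly passed and 17 no longer did. Named genera followed a rule. It took genera with a mean of at least 3% in any group. For each contrast it took the 8 largest rises and 8 largest falls in percentage points among genera that passed the test and did not overlap between groups. It also took the 4 most abundant members of each list and the 2 most abundant features of each group. Genera named outside this rule are said to be chosen after their values were seen. The lists, the rule, the tests and most alternatives were fixed before the data were examined.

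Richness was the expected number of features in a draw of 6252 reads, and the Shannon index used natural logarithms of feature shares. Both were compared by exact permutation tests on F over all 15400 partitions of 12 samples into 4 groups and all 280 partitions of the 9 run samples. Bray-Curtis distances of relative abundances were tested by PERMANOVA over the same partitions. The smallest p these can give is 6.49e-05 and 0.00357. For 3 samples against 3 there are 10 partitions and no p under 0.1. These used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures used matplotlib 3.10.9.

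Alternatives were TMM and TMMwsp factors, DESeq2 1.42.0 with poscounts size factors, limma 3.58.1 on centred log-ratios with 0.5 added to each count, no filter, a filter of 100 reads in 3 samples, only the groups compared, features, species or families in place of genera, no unnamed genera, a replicate block, other diversity indices and distances, and each sample left out in turn. Ranges and counts over the alternatives for a single genus, list or phylum leave out the replicate block, which is reported apart. A minimum confidence of 0.9 was planned but removes no feature, since the lowest confidence was 0.950, so it was not run. Leaving out 32 families and orders typical of animal guts, and adding Sphaerotilus to the PHA-storing list, were chosen after seeing the data. The test was also tested on simulated data built on the 257 genera in 5 simulations. Before changes were added, each genus had its mean share over the 12 samples in all groups. Genera absent from a whole group, or a dominant genus that differs between groups, were thus not modelled. There edgeR called 7.95% of genera given a 2-fold change, 24.9% at 4-fold, 61.5% at 8-fold, 65.5% at 16-fold and 2.21% of unchanged genera in a contrast with changes. In a contrast with none it called 0 of 1220.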

Results

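Full-length 16S rRNA gene reads were counted in 12 libraries, 3 replicates each of the Inoculum (activated sludge, the mixed flora of a wastewater plant) and of Run 1, Run 2 and Run 3 (mixed cultures fed with synthetic fermentation digestate). The libraries held 113447 reads in total. Inoculum libraries held 6252, 6396 and 7311 reads in 350, 368 and 433 features. Run 1 libraries held 9792, 10288 and 10000 reads in 31, 144 and 100 features. In Run 2 there were 11451, 9498 and 10572 reads in 169, 141 and 168 features, and in Run 3 there were 10368, 10700 and 10819 reads in 111, 96 and 96 features. Values below are percent of reads, mean ± SD with n = 3 replicates, and adjusted p-values for genera, lists and phyla come from edgeR.

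The inoculum was a diverse community whose 2 most abundant genera belonged to the Bacteroidota, whereas each run was dominated by a few genera. Ca_Epiflobacter, a protein-degrading member of the Saprospiraceae, made up 7.97% ± 1.42 of inoculum reads, and Lacihabitans, a relative of Leadbetterella in the Spirosomaceae, made up 7.62% ± 0.897. Sphaerotilus, a sheathed filamentous bacterium known from sludge bulking, held 90.0% ± 8.98 of reads in Run 1, 19.5% ± 1.501 in Run 2 and 63.0% ± 6.55 in Run 3, against 0.0208% ± 0.0361 in the inoculum. Run 2 was shared between Leadbetterella at 27.2% ± 2.31, the unnamed Rhodobacteraceae genus midas_g_11604 at 26.1% ± 2.20, and Sphaerotilus. Run 3 held Neomegalonema, a filamentous PHA-storing alphaproteobacterium, at 16.5% ± 0.662 and Pseudomonas at 7.22% ± 3.83 beside Sphaerotilus.

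**Figure D1:**
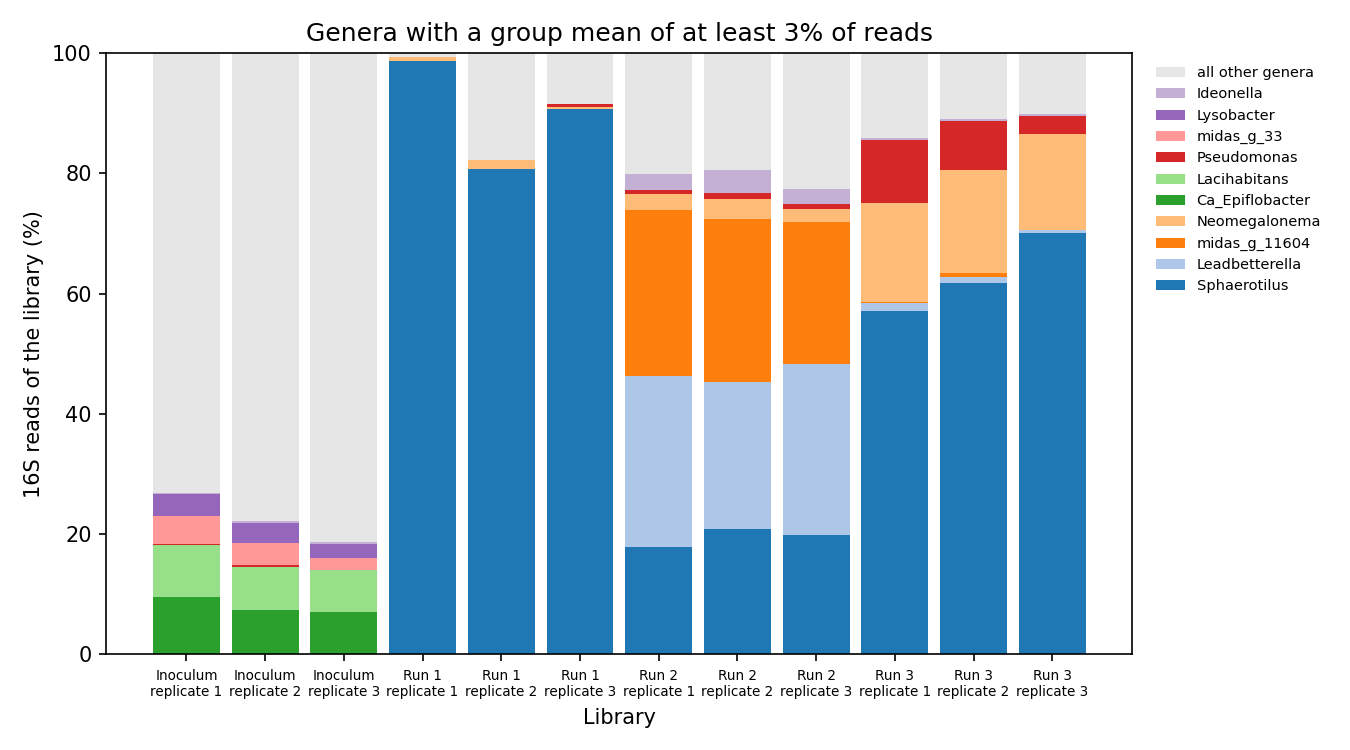
Stacked bars give the percent of 16S reads per library (12 libraries, 3 per group) in the genera with a mean of at least 3% in any group. Sphaerotilus fills 80.7% to 98.7% of the Run 1 libraries, while Leadbetterella averages 27.2% in Run 2 and Neomegalonema 16.5% in Run 3.

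At the level of phyla, Proteobacteria rose from 44.7% ± 3.6 in the inoculum to 92.1% ± 8.25 in Run 1 (log2 1.04, adjusted p = 8.64e-05) and 93.1% ± 1.45 in Run 3 (log2 1.06, adjusted p = 8.64e-05). Run 2 stood at 64.1% ± 3.02 Proteobacteria and 32.7% ± 3.16 Bacteroidota, the latter near the 31.9% ± 3.67 of the inoculum (log2 0.04, adjusted p = 1). Bacteroidota held 4.22% ± 6.16 of Run 1 and 3.48% ± 0.824 of Run 3. Patescibacteria, a phylum of very small cells with reduced genomes, held 1.97% ± 0.451 in the inoculum, 0 in Run 1 and Run 2, and 0.540%, 0.280% and 0.0739% in the Run 3 libraries. For that phylum the difference of Run 3 from the inoculum did not pass (log2 -2.72, adjusted p = 0.108, range 0.00193 to 0.353 over the alternatives). Of 133 phylum tests 52 passed, 12 of them higher in the group named first. The calls on Bacteroidota were weak: the log2 difference of 2.96 between Run 2 and Run 1 had an adjusted p of 0.044, which ranged from 9.97e-08 to 0.130 over the alternatives. Without Run 1 replicate 2 the log2 difference in Bacteroidota between Run 3 and Run 1 turned from -0.28 to 2.36. Families typical of animal guts held 11.4% of reads in that library (Wilson 95% interval 10.8 to 12.03), against 0.0306% in Run 1 replicate 1 and 3.53% in Run 1 replicate 3.

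Features per equal draw and evenness were lower in the runs. Richness at 6252 reads was 383 ± 43.2 features in the inoculum, 90.3 ± 56.2 in Run 1, 156 ± 14.9 in Run 2 and 98.7 ± 8.78 in Run 3. It differed among the 4 groups (exact permutation p = 0.00221, adjusted 0.00442) but the difference among the 3 runs did not pass (exact permutation p = 0.121). The Shannon index was 5.17 ± 0.17, 1.51 ± 0.516, 2.88 ± 0.0488 and 2.50 ± 0.157 in the same order, and differed among the 4 groups and among the runs, with the smallest exact permutation p possible in each case (6.49e-05 and 0.00357; adjusted 0.00026 and 0.00476). Without the gut-associated families, left out after seeing the data, richness in a smaller draw of 5590 reads was 342 ± 22.6, 63.6 ± 29.6, 149 ± 15.5 and 82.9 ± 9.53. The exact permutation p among the runs was then 0.0143.

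**Figure D2:**
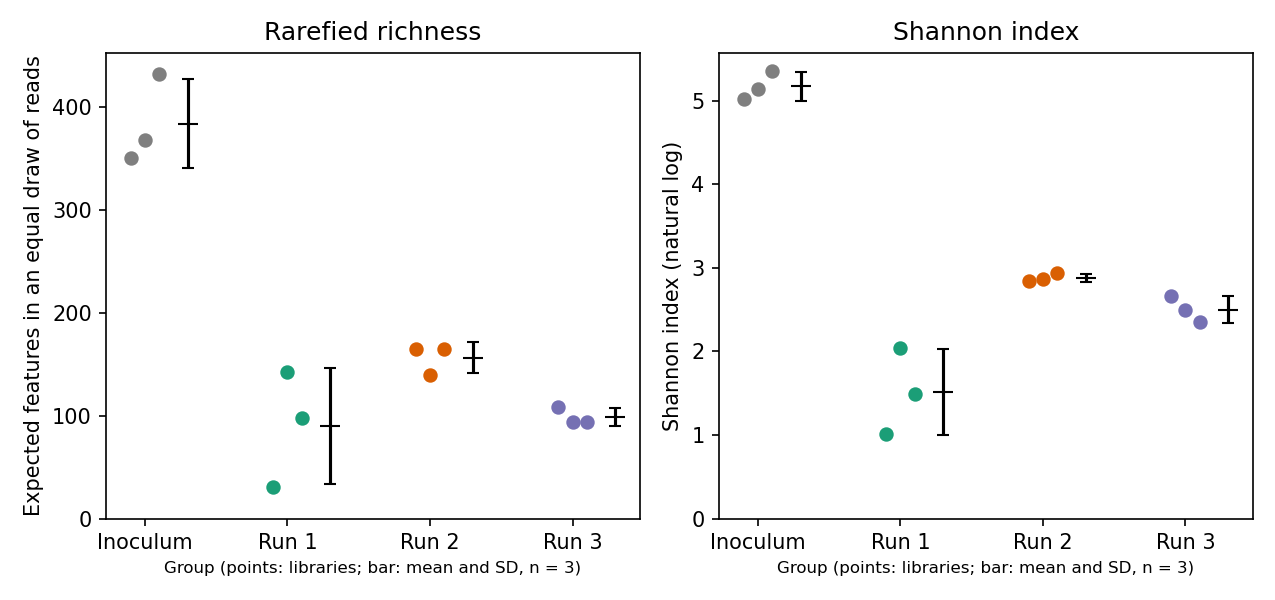
Points are single libraries and bars the mean and SD (n = 3) of richness, in expected features per draw of 6252 reads, and of the Shannon index. Inoculum libraries averaged 383 features and a Shannon index of 5.17, above each run library on both measures.

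Group identity accounted for most of the variation between communities. In a permutation test on Bray-Curtis distances, groups held 94.2% of the variation over 12 libraries and 96.4% over the 9 run libraries, both at the smallest exact p possible (6.49e-05 and 0.00357). The mean distance from the inoculum was 0.995 for Run 1, 0.999 for Run 2 and 0.996 for Run 3. Between runs it was 0.800 ± 0.0126 for Run 1 and Run 2, 0.599 ± 0.0345 for Run 1 and Run 3, and 0.743 ± 0.018 for Run 2 and Run 3. Within groups the mean was 0.376 in the inoculum and 0.158, 0.103 and 0.135 in Run 1, Run 2 and Run 3.

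**Figure D3:**
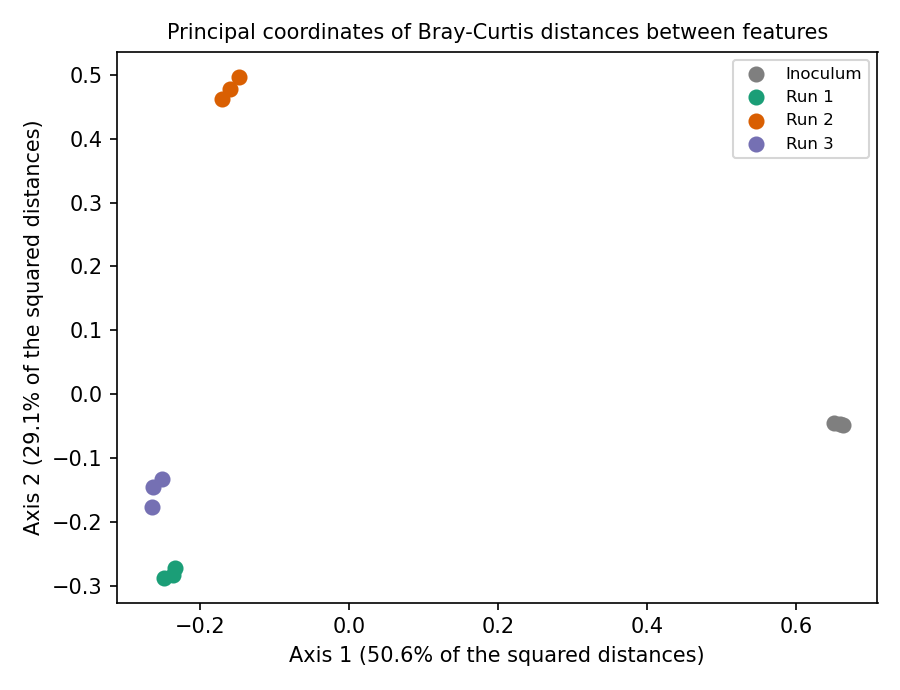
Each point is a library placed by principal coordinates of Bray-Curtis distances between features, with axes holding 50.6% and 29.1% of the squared distances. The inoculum libraries lie apart on axis 1, and Run 2 lies apart from Run 1 and Run 3 on axis 2.

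The comparison of Run 2 with Run 1 asks, as do the other pairs of runs, which taxa differ between cultures that the design places under different ratios of carbon to phosphorus. Leadbetterella, an aerobic member of the Spirosomaceae, rose from 0 in Run 1 to 27.2% ± 2.31, at least 908-fold (log2 14.33, adjusted p = 0.000172). The genus midas_g_11604 rose from 0 to 26.1% ± 2.20, at least 871-fold (adjusted p = 0.00114). Ideonella, a Burkholderiales genus, rose from 0 to 3.01% ± 0.721 (at least 100.6-fold), and Emticicia, a further Spirosomaceae genus, rose from 0 to 1.48% ± 0.202 (at least 49.5-fold). Acidovorax, a genus with PHA-storing and denitrifying members, stood at 1.24% ± 0.109 in Run 2 against 0.0872% ± 0.047 in Run 1, 14.2-fold higher (log2 3.81, adjusted p = 0.00137). The soil and water genera Devosia at 1.48% ± 0.594 and Brevundimonas at 1.20% ± 0.158, and the verrucomicrobial Terrimicrobium at 1.29% ± 0.0737, were at 0 in Run 1. Sphaerotilus, at 98.7%, 80.7% and 90.7% of the Run 1 libraries and 17.9%, 20.8% and 19.8% of the Run 2 libraries, did not pass in the fit of all 12 samples (log2 -2.21, adjusted p = 0.105). It passed when only these 6 libraries were fitted (adjusted p = 1.36e-05). It also passed, at the same log2, without Inoculum replicate 2 (2.15e-05), the only inoculum library with Sphaerotilus reads. Over the alternatives its adjusted p ranged from 1.36e-05 to 0.266, and in 13 of 21 it did not pass.

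Among the lists, PHA-storing genera rose together from 1.55% ± 0.438 in Run 1 to 34.7% ± 1.75 in Run 2 (log2 4.49, adjusted p = 1.25e-17). The list was fixed without Sphaerotilus, which is also known to store PHA, and with it, added after seeing the data, the direction turned: the sum was 91.6% ± 8.55 in Run 1 and 54.2% ± 0.979 in Run 2 (log2 -0.76, adjusted p = 0.00133). The rise is therefore one among PHA-storing genera other than Sphaerotilus. Of their 16 tested members 9 rose and 7 did not pass, or 10 rose when adjusted over the list alone. Leadbetterella supplied most of the reads, and Thauera rose to 0.115% ± 0.0312 and Azonexus to 0.301% ± 0.0568 from 0. Denitrifying sludge genera rose from 0.739% ± 0.521 to 4.31% ± 0.18 (log2 2.54, adjusted p = 8.3e-05), with 6 of 16 members higher on both adjustments. The call on this sum ended with TMM factors (log2 1.33, adjusted p = 0.0558). Bacteroidota of enrichment cultures rose from 0.186% to 29.2% ± 2.52 (log2 7.28), with 3 of 10 members higher, or 5 higher and 1 lower when adjusted over the list alone. The adjusted p of this sum was 2.54e-19 with spread pooled over lists in all samples, and 0.000926 when only the groups compared were fitted. The summed filamentous genera fell from 91.0% ± 8.52 to 22.2% ± 1.82 (log2 -2.04, adjusted p = 3.53e-13), though none of their 8 members passed over all genera and 1 rose and 1 fell when adjusted over the list alone. Without Sphaerotilus that sum was higher in Run 2 (log2 1.43). Polyphosphate-accumulating genera rose from 0 to 0.301% ± 0.0568 (log2 7.84, adjusted p = 0.00217), and the 1 of 3 members that rose was Azonexus on both adjustments. Stalked and budding bacteria rose to 1.72% ± 0.0831 from 0.0267%, with 2 of 5 members higher, Brevundimonas and Hyphomonas. Of predatory bacteria, 1 of 6 members rose, the myxobacterium Nannocystis, at 0.232% ± 0.0923 against 0. Fermentative and gut genera fell as a sum (log2 -2.39, adjusted p = 0.0237), but none of 11 members passed, and the call ended without the gut-associated families (adjusted p = 0.0617), which held 0.0306%, 11.4% and 3.53% of the Run 1 libraries. It also ended without Inoculum replicate 3 (0.0674), Run 1 replicate 2 (0.199), Run 1 replicate 3 (0.136), Run 2 replicate 1 (0.134), Run 2 replicate 2 (0.0570) or Run 3 replicate 1 (0.185). Of reagent contaminants, 1 of 4 members rose, Stenotrophomonas, at 0.407% ± 0.119 against 0. Glycogen-accumulating genera had 1 tested member, Amaricoccus, at 0.0179% against 0 (adjusted p = 0.288).

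In all, edgeR called 46 of 257 genera between Run 2 and Run 1, each of them higher in Run 2, and 66 had an unadjusted p under 0.05. Over all 257 genera the groups did not overlap in 55, the 46 included, where chance gives at most 10%, and less for genera at 0 in many libraries. With DESeq2 size factors 82.8% of calls were higher in Run 2, and on centred log-ratios 29.3% were, against 100% here. The calls on centred log-ratios include genera without reads in either run. Hydrogenophaga (log2 1.82, adjusted p = 0.0194) and Comamonas (log2 1.94, adjusted p = 0.02) lost their calls under TMM, TMMwsp, DESeq2 and centred log-ratios, with adjusted p up to 0.590 and 0.448. Without Run 1 replicate 1 their adjusted p was 0.0644 and 0.0643, and without Run 1 replicate 2 it was 0.0592 and 0.0660. Comamonas and Hyphomonas ended without Run 2 replicate 3 (both 0.0565), and so did Azonexus (0.0565), which also ended without Inoculum replicate 3 (0.0568). Acidovorax ended with DESeq2 (adjusted p = 0.0654).

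Run 3 differed from Run 1 first in Neomegalonema, which rose from 0.837% ± 0.586 to 16.5% ± 0.662, 19.8-fold (log2 4.30, adjusted p = 0.00146). Azoarcus at 1.28% ± 0.131 and Thauera at 1.23% ± 0.541, both Rhodocyclales genera with denitrifying and PHA-storing members, rose from 0 (at least 42.8-fold and 41.1-fold). Leadbetterella reached 0.937% ± 0.41 and Emticicia 0.630% ± 0.21 from 0. The unnamed Bdellovibrionaceae genus midas_g_65428, from a family of bacterial predators, rose from 0 to 0.674% ± 0.0804 (at least 22.5-fold, adjusted p = 0.00319), and Nannocystis rose from 0 to 0.717% ± 0.406. Sphaerotilus stood at 57.1%, 61.8% and 70.0% in the Run 3 libraries, below each Run 1 library, but did not pass (log2 -0.52, adjusted p = 1). It passed when only these 6 libraries were fitted (adjusted p = 0.0225), and its log2 difference turned to 0.06 with TMMwsp factors. Pseudomonas, a genus of aerobic and denitrifying bacteria, stood at 7.22% ± 3.83 against 0.173% ± 0.3 and did not pass (log2 5.37, adjusted p = 0.170, range 0.00793 to 0.361 over the alternatives).

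Between these runs the PHA-storing list rose from 1.55% ± 0.438 to 29.0% ± 5.91 (log2 4.22, adjusted p = 1.34e-16), with 6 of 16 members higher, or 8 when adjusted over the list alone. With Sphaerotilus added to the list the sums of 91.6% ± 8.55 and 92.0% ± 1.10 did not differ by the test (log2 0.01, adjusted p = 1). Its members Neomegalonema, Thauera and Azoarcus passed, and Zoogloea rose from 0 to 0.154% ± 0.0459. Denitrifying sludge genera rose to 11.5% ± 5.13 (log2 3.96, adjusted p = 1.7e-08), with 4 of 16 members higher, or 5 over the list alone. The filamentous sum was 79.6% ± 6.18 against 91.0% ± 8.52 and did not pass (log2 -0.19, adjusted p = 0.446), and 1 of 8 members rose, Neomegalonema. Without Sphaerotilus the filamentous sum was higher in Run 3 (log2 4.08). Predatory bacteria, a list that does not hold midas_g_65428, rose from 0.0133% to 0.780% ± 0.433 (log2 5.74, adjusted p = 0.000175), with 1 of 6 members higher, or 2 over the list alone. Bacteroidota of enrichment cultures rose to 2.33% ± 0.886 with 2 of 10 members higher. For fermentative and gut genera the sums of 1.28% ± 1.2 and 1.11% did not differ by the test (log2 -0.20, adjusted p = 0.864).

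In edgeR 22 of 257 genera were called between Run 3 and Run 1, each higher in Run 3 and among the 33 without overlap, and 44 had an unadjusted p under 0.05. Comamonas, 4.90-fold higher in Run 3 (log2 2.28, adjusted p = 0.0153), lost its call with TMM factors (0.106) and without Run 1 replicate 1 (0.0584), Run 1 replicate 2 (0.0623), Run 3 replicate 1 (0.0589) or Run 3 replicate 2 (0.0515).

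Between Run 3 and Run 2 the dominant companions of Sphaerotilus changed. Leadbetterella fell from 27.2% ± 2.31 in Run 2 to 0.937% ± 0.41 in Run 3, 29.0-fold lower (log2 -4.86, adjusted p = 0.00241), and midas_g_11604 fell from 26.1% ± 2.20 to 0.279% ± 0.248, 93.4-fold lower (log2 -6.54, adjusted p = 0.00519). Ideonella was 8.22-fold lower and Acidovorax 14.6-fold lower in Run 3, and Terrimicrobium and the unnamed Rhodobacteraceae genus midas_g_51 fell to 0 from 1.29% ± 0.0737 and 0.966% ± 0.0996. Neomegalonema rose from 2.63% ± 0.535 to 16.5% ± 0.662, 6.28-fold (log2 2.65, adjusted p = 0.00846), and Thauera rose 10.7-fold (log2 3.40, adjusted p = 0.00264). Inhella, midas_g_65428 and Zoogloea, a floc-forming genus, were at 0 in Run 2 and at 0.256% ± 0.123, 0.674% ± 0.0804 and 0.154% ± 0.0459 in Run 3. Sphaerotilus was higher in each Run 3 library than in each Run 2 library yet did not pass (log2 1.69, adjusted p = 0.2397). It passed when only these 6 libraries were fitted (adjusted p = 0.000248) and without Inoculum replicate 2 (0.000528), the only inoculum library that held it. Pseudomonas, at 0.823% ± 0.186 in Run 2, did not pass (log2 3.13, adjusted p = 0.362) but passed in the fit of only these 6 libraries (0.00117).

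The PHA-storing sums of 34.7% ± 1.75 in Run 2 and 29.0% ± 5.91 in Run 3 did not differ by the test (log2 -0.26, adjusted p = 0.514), while 4 of 16 members rose and 4 fell, or 4 and 5 when adjusted over the list alone. Without Leadbetterella the sum was higher in Run 3 (log2 1.89), and so was the sum with Sphaerotilus (log2 0.76, adjusted p = 0.00125). Among filamentous genera, whose sum rose from 22.2% ± 1.82 to 79.6% ± 6.18 (log2 1.84, adjusted p = 1.57e-11), 1 of 8 members passed, Neomegalonema. Polyphosphate-accumulating genera fell from 0.301% ± 0.0568 to 0.0129% ± 0.0223 (log2 -4.43, adjusted p = 0.0191), with none of 3 members passing. That fall ended without Inoculum replicate 2 (0.0612), Inoculum replicate 3 (0.0548), Run 3 replicate 2 (0.0660) or Run 3 replicate 3 (0.0629). Bacteroidota of enrichment cultures fell from 29.2% ± 2.52 to 2.33% ± 0.886 (log2 -3.65, adjusted p = 1.48e-09) with 1 of 10 members lower, or 1 higher and 5 lower over the list alone, and without Leadbetterella the sum no longer passed (log2 -0.50, adjusted p = 0.487). Denitrifying sludge genera rose (log2 1.42, adjusted p = 0.0191), with 3 members higher and 2 lower, or 3 and 3 over the list alone. That call ended without the most abundant member (adjusted p = 0.551) and without Run 2 replicate 1 (0.0606), Run 2 replicate 2 (0.0571), Run 2 replicate 3 (0.0620), Run 3 replicate 1 (0.10004) or Run 3 replicate 2 (0.0672). Fermentative and gut genera rose as a sum from 0.242% to 1.11% (log2 2.19, adjusted p = 0.0356), with none of 11 members passing, and the call ended without the gut-associated families (adjusted p = 0.290), which held 0.236%, 0.695% and 0.946% of the Run 2 libraries and 2.20%, 0.822% and 2.97% of the Run 3 libraries. With 1 library left out it held without Run 1 replicate 1, Run 1 replicate 3 or Run 3 replicate 2, and ended without any other single library (adjusted p up to 0.241, without Run 3 replicate 1).

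In this pair 43 of 257 genera were called by edgeR, 12 higher and 31 lower in Run 3, all among the 60 without overlap, and 62 had an unadjusted p under 0.05. Among DESeq2 calls 40.9% were higher, against 27.9% here. Of the genera named, Neomegalonema ended without Run 2 replicate 3 (log2 2.52, adjusted p = 0.0524). Azoarcus, at 1.28% ± 0.131 in Run 3 and 0.00946% in Run 2 (log2 6.89, adjusted p = 0.0192), ended without Run 3 replicate 1 (0.0550). Devosia, at 0.00616% in Run 3 (log2 -7.61, adjusted p = 0.0192), ended without Run 2 replicate 3 (0.0543), Run 3 replicate 1 (0.0713) or Run 3 replicate 2 (0.0677). Over all 3 runs the F test called 61 genera, and 77 had an unadjusted p under 0.05.

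**Figure D4:**
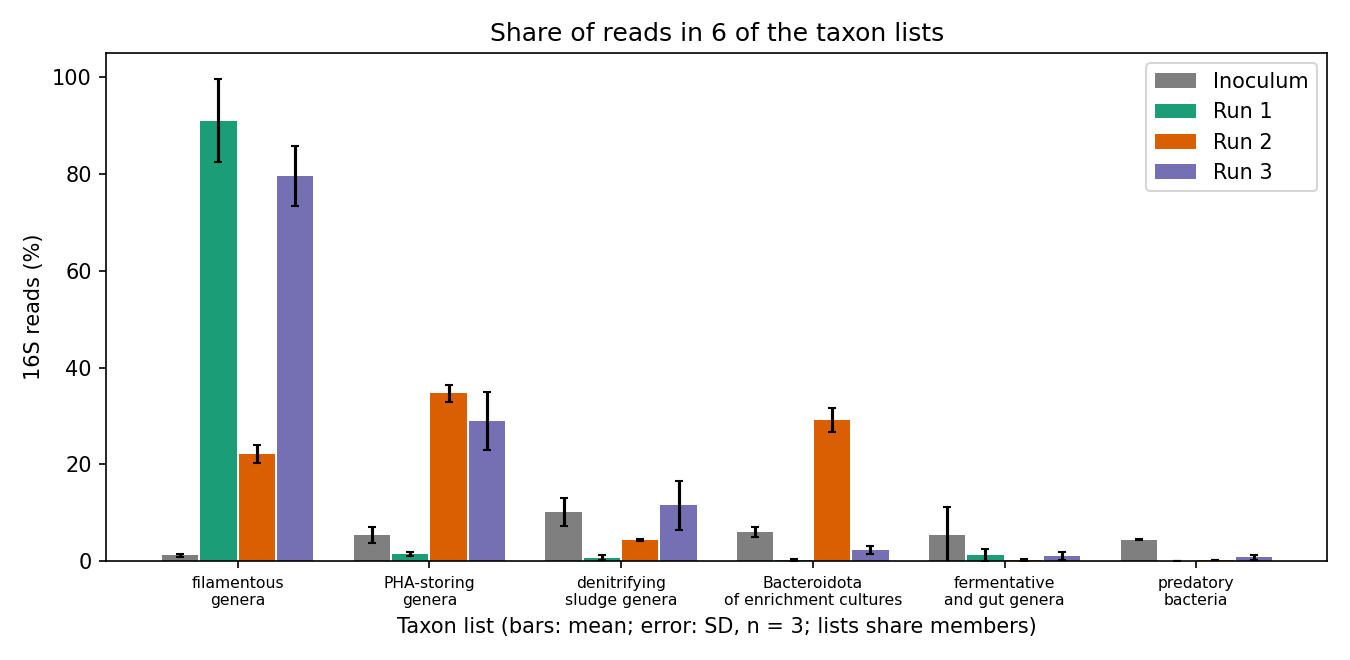
Bars give the mean percent of 16S reads in 6 of the taxon lists per group, with SD (n = 3), and lists share members. Filamentous genera hold 91.0% of Run 1 and 22.2% of Run 2, and PHA-storing genera, a list fixed without Sphaerotilus, 1.55%, 34.7% and 29.0% of Run 1, Run 2 and Run 3.

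The comparison with the inoculum asks which taxa differ between the sludge and the fed cultures. Taking the mean of the 3 runs, 163 genera fell and 3 rose: Sphaerotilus (log2 11.10, adjusted p = 0.000155), Neomegalonema (log2 11.29, adjusted p = 9.53e-05) and Comamonas (log2 1.30, adjusted p = 0.0228). All 3 had reads in each run. Genera at 0 in the inoculum and in Run 1, such as Leadbetterella (log2 7.93), midas_g_11604 (log2 7.33) and Emticicia (log2 6.34), were not called by edgeR (adjusted p = 0.9998 each). The imbalance of 163 to 3 therefore says little about rises confined to some runs. Ca_Epiflobacter and Lacihabitans fell to 0 in each run library, at least 275-fold and 263-fold lower. Lysobacter, a gliding bacterium that lyses other microbes, fell from 3.14% ± 0.647 to 0 (at least 108-fold), as did the unnamed Comamonadaceae genera midas_g_33 from 3.45% ± 1.36 and midas_g_887 from 2.51% ± 0.811, and the Rhodocyclaceae genus Azospira from 2.20% ± 0.467. Thermomonas, a denitrifying genus of sludge, fell from 2.76% ± 0.296 to 0.0332%, 83.1-fold (log2 -6.79), and Zoogloea was 42.1-fold lower than its 2.16% ± 1.25. Ca_Accumulibacter, the best known polyphosphate-accumulating organism, was at 0.549% ± 0.249 in the inoculum and 0 in the runs (at least 19.0-fold lower, adjusted p = 0.000375). Cutibacterium, a skin genus also known from reagents, held 2.07% ± 0.784 of the inoculum and 0 of the runs.

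Most lists lost members between the inoculum and the mean of the runs, with the same counts over all genera and adjusted over the list alone. Of filamentous genera 6 of 8 members fell and 2 rose, Sphaerotilus and Neomegalonema, while the sum rose (log2 5.43, adjusted p = 1.77e-36). PHA-storing genera had 2 members higher and 5 lower of 16, with a higher sum (log2 1.11, adjusted p = 0.00133) that no longer passed without Leadbetterella (log2 0.36, adjusted p = 0.256). With Sphaerotilus on the list the sum was higher by a log2 of 3.83. Denitrifying sludge genera had 8 lower and 1 higher of 16 (sum log2 -1.61, adjusted p = 0.000422; with TMM factors -0.55, adjusted p = 0.327). Among Bacteroidota of enrichment cultures 6 of 10 fell, among predatory bacteria 4 of 6 (sum log2 -4.99, adjusted p = 6.86e-08), and among polyphosphate-accumulating genera 2 of 3 (sum log2 -5.37, adjusted p = 8.3e-05). The predatory sum leaves out midas_g_65428, seen only in Run 3. Of reagent contaminants 3 of 4 members fell, of stalked and budding bacteria 1 of 5 (Pirellula, a call that ended without Inoculum replicate 3, at 0.101), and the 1 organelle genus, a chloroplast group, fell from 0.251% ± 0.0264. Nitrifying genera were at 0.03% in the inoculum and 0 in the runs, in Nitrospira and Nitrosomonas, both below the filter (sum adjusted p = 0.0116). That call ended without Inoculum replicate 2 (0.186) or Inoculum replicate 3 (0.146), and so did the fall in glycogen-accumulating genera (log2 -3.23, adjusted p = 0.0251), at 0.157 and 0.1200. Of fermentative and gut genera 5 of 11 fell, Blautia, Bifidobacterium, Bacteroides, Trichococcus and Turicibacter, the last named after its value was seen. Without Inoculum replicate 3 the calls ended for Bacteroides (log2 from -3.91 to -1.45, adjusted p from 0.0332 to 0.570), Blautia (log2 from -7.29 to -1.80, adjusted p from 0.00846 to 0.438) and Turicibacter (adjusted p from 0.0241 to 0.0660). Turicibacter also ended without Inoculum replicate 1 (0.130). Bacteroides also ended without Inoculum replicate 1 (0.0526), Run 1 replicate 3 (0.0508), Run 2 replicate 1 (0.0504), Run 2 replicate 2 (0.0505), Run 3 replicate 1 (0.0634) or Run 3 replicate 3 (0.0597), and kept its call in 8 of 19 alternatives. The sum of the list fell from 5.44% ± 5.82 (log2 -2.96, adjusted p = 8.44e-05), ended without Inoculum replicate 3 (adjusted p = 0.137), and moved with gut-associated families at 7.20%, 12.6% and 15.9% of the inoculum libraries.

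By edgeR 166 genera were called for the mean of the runs, and 169 had an unadjusted p under 0.05. In 117 of the 257 genera all 9 run libraries lay on 1 side of all 3 inoculum libraries, where chance gives at most 0.909%, and all 117 were called. Leadbetterella, at 0 in Run 1 and in the inoculum, was not called by edgeR (log2 7.93, adjusted p = 0.9998) but was called higher by DESeq2 (log2 8.36, adjusted p = 3.45e-08) and on centred log-ratios (log2 8.96, adjusted p = 1.06e-09). Likewise DESeq2 called midas_g_11604 (log2 7.77, adjusted p = 8.43e-06) and Emticicia (log2 6.78, adjusted p = 9.58e-06) higher. Ideonella, at 0 in Run 1, is called lower (log2 -1.08, adjusted p = 0.0249) although its mean percent over the run libraries, 1.13%, is above the 0.239% ± 0.041 of the inoculum. It is the only 1 of the 163 genera with this contrast, and its direction turned with TMMwsp, DESeq2 and centred log-ratios. That call ended without Inoculum replicate 3 (0.0573), Run 1 replicate 1 (0.0606), Run 1 replicate 2 (0.0620) or Run 1 replicate 3 (0.0612). Calls higher made up 22.7% with DESeq2 and 39.3% on centred log-ratios, against 1.81% here. Comamonas ended without Inoculum replicate 1 (adjusted p = 0.0640) or Inoculum replicate 3 (0.0867).

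Taken run by run, Run 1 had 2 genera above the inoculum and 124 below. The genera above were Sphaerotilus, 4319-fold higher than an inoculum level that rests on 4 reads in Inoculum replicate 2 (log2 12.01, adjusted p = 0.000151), and Neomegalonema, at least 18.5-fold higher (log2 9.31, adjusted p = 0.000157). PHA-storing genera fell as a sum from 5.39% ± 1.7 to 1.55% ± 0.438 (log2 -1.80, adjusted p = 1.43e-05), with 1 of 16 members higher and 6 lower on both adjustments, but not with TMM factors (log2 -0.11, adjusted p = 0.883). With Sphaerotilus on the list the direction turned, from 5.41% ± 1.70 to 91.6% ± 8.55 (log2 4.08, adjusted p = 6.66e-30). Denitrifying sludge genera had 10 of 16 members lower and predatory bacteria 5 of 6. Of 257 genera 126 were called by edgeR, 150 had an unadjusted p under 0.05, and 39.5% of calls were higher on centred log-ratios, against 1.59% here.

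Run 2 held 39 genera above the inoculum and 120 below. Leadbetterella and midas_g_11604 rose from 0, at least 600-fold and 576-fold, Ideonella rose 12.6-fold from 0.239% ± 0.041, Neomegalonema rose at least 58.1-fold, and Sphaerotilus 936-fold (log2 9.81, adjusted p = 0.000396). PHA-storing genera rose as a sum (log2 2.69, adjusted p = 1.13e-09) with 5 of 16 members higher and 4 lower on both adjustments, though not without Leadbetterella (log2 0.49, adjusted p = 0.194). The sum of stalked and budding bacteria did not pass (log2 2.49, adjusted p = 0.079), nor did it in 12 of 18 alternatives (range 0.00253 to 0.510). It passed with TMM factors (0.0114). Of the 5 members of this list 3 were higher and none lower, or 1 lower over the list alone. Of the 3, Brevundimonas and Hyphomonas kept their calls with each library left out, while Verrucomicrobium (adjusted p = 0.0395) ended with DESeq2 and without Inoculum replicate 1 (0.0774), Inoculum replicate 2 (0.0585), Inoculum replicate 3 (0.0951), Run 2 replicate 2 (0.0804) or Run 2 replicate 3 (0.0777). Polyphosphate-accumulating genera, at 0.301% ± 0.0568 against 0.732% ± 0.197, did not pass as a sum (log2 -1.28, adjusted p = 0.422), with 1 of 3 members lower, Ca_Accumulibacter. In edgeR 159 genera were called and 184 had an unadjusted p under 0.05, and calls higher made up 38.2% with DESeq2 and 37.9% on centred log-ratios, against 24.5% here.

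Run 3 held 21 genera above the inoculum and 123 below. Neomegalonema rose from 0 at least 365-fold (log2 13.61, adjusted p = 7.61e-05), Sphaerotilus rose 3021-fold (log2 11.50, adjusted p = 0.00026), and Azoarcus, Leadbetterella and midas_g_65428 rose from 0 by at least 28.3-fold, 20.7-fold and 14.9-fold. Pseudomonas was 59.8-fold higher (log2 5.89, adjusted p = 0.0315), a call that ended without Inoculum replicate 1 (0.0985), Inoculum replicate 3 (0.0728), Run 3 replicate 1 (0.0651) or Run 3 replicate 2 (0.0537). PHA-storing genera rose as a sum (log2 2.43, adjusted p = 1.7e-08) with 5 of 16 members higher and 4 lower on both adjustments. Denitrifying sludge genera, at 11.5% ± 5.13 against 10.1% ± 2.92, did not pass as a sum (log2 0.18, adjusted p = 0.784), with 3 members higher and 8 lower. Without its most abundant member that sum turned and passed (log2 -1.22, adjusted p = 0.0167). By edgeR 144 genera were called and 172 had an unadjusted p under 0.05, and calls higher made up 42.9% with DESeq2 and 36.8% on centred log-ratios, against 14.6% here.

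The leading features came from the leading genera of each group, though in the inoculum in the reverse order. In the inoculum the most abundant were a Lacihabitans feature at 6.28% ± 0.808 and a Ca_Epiflobacter feature at 5.61% ± 1.03. In Run 2 a Leadbetterella byssophila feature held 26.9% ± 2.07 and a midas_g_11604 feature 24.6% ± 1.96. In Run 1 the leaders were 2 features assigned to Sphaerotilus natans, feature 1 at 68.7% ± 5.98 and feature 2 at 8.68% ± 1.65, and in Run 3 feature 2 stood at 22.2% ± 1.31 and feature 1 at 20.8% ± 3.09. Among Sphaerotilus reads alone, feature 1 made up 76.3% ± 0.983 in Run 1, 44.4% ± 0.881 in Run 2 and 32.9% ± 1.56 in Run 3, and feature 2 made up 9.59% ± 1.0, 28.2% ± 0.725 and 35.4% ± 1.74. Feature 1 differed among the 3 runs at the smallest exact permutation p possible, 0.00357.

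**Figure D5:**
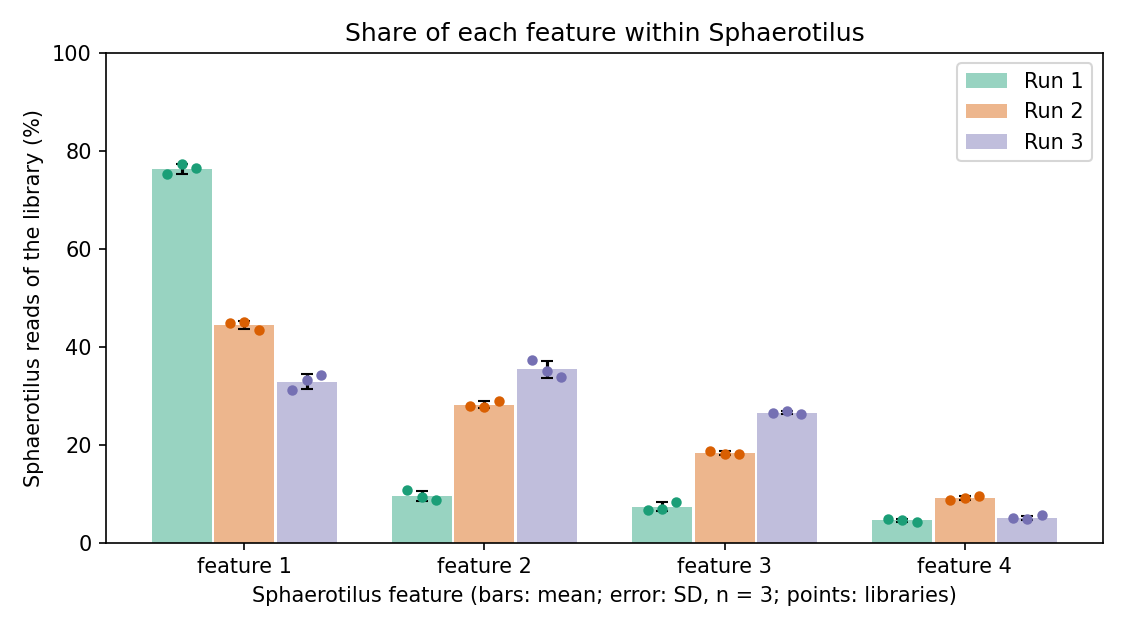
Bars give the mean percent of a library's Sphaerotilus reads in each of its 4 most abundant features, with SD (n = 3) and points for libraries. Feature 1 holds 76.3% of them in Run 1, 44.4% in Run 2 and 32.9% in Run 3.

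Few features were shared between the runs and the inoculum. Of 228, 262 and 180 features in Run 1, Run 2 and Run 3, 20, 7 and 10 were among the 698 of the inoculum, and these held 1.22% ± 1.15, 0.58% ± 0.161 and 0.978% ± 0.748 of run reads. Genera overlapped more: 48 of 81, 50 of 113 and 42 of 80 were among the 351 of the inoculum. They held 96.9% ± 3.04, 32.9% ± 2.35 and 77.9% ± 1.76 of run reads, and 65.5% ± 12.5, 16.7% ± 1.35 and 39.6% ± 6.39 of those outside Sphaerotilus. Between runs, 12 features were shared by Run 1 and Run 2, 20 by Run 1 and Run 3, and 70 by Run 2 and Run 3.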

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

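Of the tests below, only those without gut-associated families and with Sphaerotilus among the PHA-storing genera were chosen after the results were seen. Both PERMANOVA results and both Shannon results kept their side of the threshold under each alternative run (for Shannon these include 2 other measures, inverse Simpson and Pielou evenness), with R2 of 0.938 to 0.962 (4 groups) and 0.959 to 0.974 (runs) and exact permutation p up to 0.000584 and 0.0321 with 1 library left out. Passing list totals stayed within 39 to 59 of 84, against 58. Named genera kept their side of the threshold, with no reversed direction that passed in either setting, in 279 of 306 cases with TMM. They did so in 270 with TMMwsp, 238 with DESeq2 and 233 on centred log-ratios, and in 3491 of 3672 cases with 1 library left out. With the replicate number as a block, 224 of 306 cases were kept and 82 lost their call. Changes of sign that passed in neither setting count as kept here. Against the inoculum the median log2 difference of all genera for the mean of the runs was -5.52 with total reads, -4.69 with TMM, -4.23 with TMMwsp, -3.76 with DESeq2 and -0.48 on centred log-ratios, which moved the medians of the pairs of runs from 0 to -1.03 (Run 2 and Run 1), -0.54 (Run 3 and Run 1) and 0.48 (Run 3 and Run 2). In the simulated data genera changed 2-fold or 4-fold were mostly missed (7.95% and 24.9% called), and at 16-fold 65.5% were called. Those data held neither the absent genera nor the unequal dominance of the real groups, so the rates need not hold here.

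DESeq2 gave 29 genera for Run 2 and Run 1, 22 for Run 3 and Run 2, 66 for the mean of the runs and the inoculum, 31, 68 and 49 for Run 1, Run 2 and Run 3 against it, and 37 among the runs. Centred log-ratios gave 164 genera for Run 2 and Run 1 and 151 among the runs. The cause of the DESeq2 counts was not tested. On centred log-ratios a genus at 0 in every run library, such as Ca_Epiflobacter, differs between runs only by the sample means subtracted. Calls on this scale include such genera, so these counts are not counts of taxa seen to differ. A filter of 100 reads in 3 samples left 84 genera to test and gave 25 for Run 3 and Run 2, 48 for the mean of the runs, 47, 62 and 49 for Run 1, Run 2 and Run 3 against the inoculum, and 33 among the runs. Features in place of genera (454 tested) gave 82 for Run 2 and Run 1, 38 for Run 3 and Run 1, 80 for Run 3 and Run 2, 253 for the mean of the runs, 247 for Run 2 and the inoculum and 94 among the runs. Families (121 tested) gave 27, 9 and 22 for those pairs of runs, 79 for the mean of the runs, 57, 60 and 64 for Run 1, Run 2 and Run 3 against the inoculum, and 34 among the runs. Neither for the filter nor for the rank was the cause tested.

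With the replicate number as a block, edgeR called 10 genera for Run 2 and Run 1, 10 for Run 3 and Run 1, 3 for Run 3 and Run 2, 107 for the mean of the runs, 29, 38 and 30 for Run 1, Run 2 and Run 3 against the inoculum, and 16 among the runs, and 30 phylum totals passed. Correlations between samples of the same number ran from -0.294 to 0.196. Above the 0.1 set as needed for pairing were Inoculum and Run 1 at replicates 1 (0.179) and 2 (0.167). So was Run 1 and Run 2 at replicate 1 (0.196). The correlations thus gave no consistent pairing by number but do not exclude it. A block leaves fewer residual degrees of freedom.

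With each library left out in turn, counts ranged from 34 to 50 for Run 2 and Run 1, 17 to 25 for Run 3 and Run 1, 25 to 45 for Run 3 and Run 2 (25 without Run 2 replicate 3), 132 to 170 for the mean of the runs, 119 to 134, 150 to 173 and 138 to 156 for Run 1, Run 2 and Run 3 against the inoculum, and 41 to 60 among the runs. Phylum totals ranged from 28 to 56 against 52, with 32 without Inoculum replicate 1, 34 without Inoculum replicate 3, 31 without Run 2 replicate 1 or Run 2 replicate 2, and 28 without Run 3 replicate 1. Where 2 replicates remained in a group, edgeR pooled the spread over groups.

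Richness among the 3 runs, with an exact permutation p of 0.121, passed without features under 10 reads (0.0179), for genera (0.00357) and without gut-associated families (0.0143). Inverse Simpson (0.0179) and Pielou evenness (0.00714), planned as alternatives, also passed, but they do not measure richness, and inverse Simpson placed Run 3 (7.20) above Run 2 (6.80). With 1 library left out the exact p ranged from 0.0107 to 0.289, at 0.0429 without Run 1 replicate 1 and 0.0107 without Run 1 replicate 2.

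Where a result passed the test in at least 1 of the 2 settings, directions that reversed were these log2 values, whose cause was not tested unless stated. A further 149 changes of sign passed in neither setting, such as that of Sphaerotilus in Run 3 and Run 1 with TMMwsp, and are not listed. With TMM, Run 1 against the inoculum gave Acidovorax 0.15 and Comamonas 1.49. With TMMwsp, Ideonella was 0.61 for the mean of the runs and Acidovorax 0.31 for Run 3 against the inoculum. With DESeq2, Ideonella was 0.42 for the mean of the runs and Acidovorax 0.33 for Run 1 against the inoculum. Centred log-ratios gave, for the mean of the runs, Acidovorax 2.38, Bacteroides 0.44, Ideonella 2.47, Inhella 0.35, Nannocystis 3.17 and Thauera 0.27. On that scale Run 1 against the inoculum gave Acidovorax 1.53, Azonexus 0.22, Brevundimonas 0.52, Comamonas 3.26 and Hydrogenophaga 2.70, Run 2 gave Thauera 0.20 and Run 3 gave Acidovorax 1.13. With each library left out, Pseudomonas in Run 1 against the inoculum ranged from -6.51 (without Run 1 replicate 3, the only Run 1 library that held it) to 1.85, and Bacteroidota in Run 3 against Run 1 from -0.85 to 2.36 (without Run 1 replicate 2). Without the most abundant member, whose removal is itself the cause, the filamentous list gave 1.43 (Run 2 and Run 1), 4.08 (Run 3 and Run 1) and -0.34 (Run 1 and the inoculum), PHA-storing genera 1.89 (Run 3 and Run 2), Bacteroidota of enrichment cultures -1.59 (Run 2 and the inoculum) and denitrifying sludge genera -1.22 (Run 3 and the inoculum). With Sphaerotilus among them, which is itself the cause, PHA-storing genera gave -0.76 (Run 2 and Run 1), 0.76 (Run 3 and Run 2) and 4.08 (Run 1 and the inoculum).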

Other observations

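Of the tests reported here, the test of read totals and the test of features found in at least 2 libraries for Run 1, both Sphaerotilus tests, and the tests by single run of gut-associated features and of genera shared with the inoculum, were chosen only after the result was seen. A small core of features ran through the cultures: 10 features were found in all 3 runs, and 2 in all 4 groups. These 10 held 97.0%, 81.0% and 89.3% of reads in the Run 1 libraries, 20.1%, 23.4% and 22.0% in Run 2, and 68.2%, 73.2% and 79.6% in Run 3. Fusobacterium, an anaerobe of animal mouths and guts outside the naming rule and chosen after its value was seen, held 4.13% of reads in Inoculum replicate 2 (Wilson 95% interval 3.67 to 4.64) and 0 in the other inoculum libraries. The family Christensenellaceae, also chosen after its values were seen, was found in each Run 2 library, at 0.166%, 0.253% and 0.255%, and at 0 in the other libraries. Of the gut-associated reads in Run 1, Run 1 replicate 2 held Muribaculaceae, a family of the mouse gut, at 5.36%, Lactobacillaceae at 1.29%, Prevotellaceae at 1.14% and Rikenellaceae at 0.826%, while Run 1 replicate 3 held Lactobacillaceae at 2.93%.

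For the 31, 144 and 100 features of the Run 1 libraries, the gut-associated shares were 0.0306%, 11.4% and 3.53%. Unequal depth is argued against, since expected features grow no faster than reads and the largest total of reads was 1.05 times the smallest. Without the listed gut-associated families the libraries held 30, 82 and 83 features, a ratio of 2.77. Reads of those families are therefore argued against as the whole source of the unequal numbers. Bacteroidales without a family name, at a mean of 1.16% of Run 1 reads, are outside that list. Gut bacteria beyond the list were not tested. Among features found in at least 2 of the 12 libraries the counts were 24, 40 and 39, a ratio of 1.67, which lies between the bounds set for the test and leaves features private to 1 library (14.4% and 5.4% of reads in Run 1 replicate 2 and Run 1 replicate 3) open. For the gut-associated reads, a resident population shared by the replicates is argued against for Run 1 only: 4 of 53 such features with at least 10 reads in a library (7.55%) were found in another replicate, against 39 of 78 (50%) of other features. In Run 2, where Christensenellaceae were in each library, and in Run 3 it was 3 of 7 (42.9%) and 7 of 20 (35%), which leaves it open there, and the 17.5% over all runs rests on Run 1. Reads carried over from other samples stay open as untested, and no other biological explanation was tested, since no label distinguishes the replicates.

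Sphaerotilus reads fell into 42 features, of which 4 held 98.8%, in proportions that differed between runs. Counting error is argued against by a chi-square per degree of freedom of 1766 between the runs. Gene copies of a single genome, or errors from a single template, would keep constant proportions if amplified and denoised alike in each run. On that condition they are argued against: the share of feature 1 spanned 36.8 pooled SD between run means. Of 6 ratios between the 4 features, that of 2 to 3, picked after the values were seen, varied least, at 1.33 ± 0.271, 1.54 ± 0.0613 and 1.33 ± 0.0665 in Run 1, Run 2 and Run 3, and that of 2 to 4 was 2.10, 3.09 and 7.02. A candidate explanation is that more than 1 Sphaerotilus strain was present, a hypothesis that these data cannot separate from differences between runs in amplification or denoising.

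Little feature overlap between runs and inoculum could reflect features split by denoising while genera still overlap. Run reads outside Sphaerotilus lay in genera detected in the inoculum for 40.6% on average, between the bounds of 25 and 50 set for the test, but the runs differed. For Run 2 it is argued against as the main source, at 16.7% ± 1.35, and for Run 1 (65.5% ± 12.5) and Run 3 (39.6% ± 6.39) it stays open. Organisms too rare in the sludge to be seen at 6252 to 7311 reads also stay open, as Sphaerotilus itself was seen in the inoculum in 4 reads, as does entry of other organisms with the feed, which was not tested.

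Regroupings of the libraries test whether groups of this size call as many genera by chance. For the F test among the runs, 1 of 100 drawn splits, the real one, reached 61 genera, and the highest other reached 21. For the mean of the runs against the inoculum, 1 of 100 drawn assignments reached 166, the highest other reaching 20. A random grouping of these libraries is argued against as the source of both counts. If replicates are repeated samples of 1 culture, regrouping cannot tell an effect of the conditions from a chance difference between single cultures. For each pair of groups 10 splits are too few for a share under 0.05. The real split and the highest other called 46 and 1 genera for Run 2 and Run 1, 22 and 0 for Run 3 and Run 1, and 43 and 0 for Run 3 and Run 2. Against the inoculum they called 126 and 0 for Run 1, 159 and 0 for Run 2, and 144 and 0 for Run 3, in each case with 1 split, the real one, at that count.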
